A study of Rattus norvegicus with 89 samples.

How the data were processed

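Exfoliated colon cells in the feces of Sprague Dawley rats were measured on 89 CodeLink arrays. Per the labels' protocols, the rats were housed individually, ate an FO/P or a CO/C diet and were injected subcutaneously with azoxymethane, 2 injections of 15 mg/kg. Per the labels' protocols too, poly(A) RNA was enriched from fecal total RNA on oligo dT columns, amplified with a MessageAmp II kit, labelled with biotin and hybridized, 1 sample per array. The meaning of CO/C is not given in the sources used here.

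Each sample file held 35974 spots with 5 measures per spot. Per the file headers, the authors deposited the mean spot intensity, the median intensity of the local background, a raw intensity, a normalized intensity and a quality flag. The deposited raw intensity equalled the spot mean minus the background median, and the normalized intensity equalled the raw intensity times a single factor per array (largest relative spread of that factor 8.3e-05). The deposited series table was the same as the normalized intensity of the sample files (largest difference 0), so fits on either give the same result and are given once. All deposited intensity values are on a linear scale.

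All steps started from the deposited spot intensity and its background. Spots that the scanner had masked (19 to 167 per array) or marked as irregular or contaminated (102 to 4594 per array) were set to missing. Background was corrected with limma's normexp method at an offset of 50, values were put on the log2 scale and quantile normalized between arrays. The offset narrows log2 differences of dim probes, so folds given here are folds of this signal and not of RNA amount. Of the spots, 2013 control spots were left out, 845 of them blank, repeated spots of 28 probes were averaged, and 33877 probes remained. Gene symbols came from the array annotation and were checked by gene identifier against the reference gene list. In all, 16781 probes had 1 symbol, 165 several and 16931 none, for 12199 symbols. A spot was counted as above background when its flag marked it neither as near background nor as masked, irregular or contaminated; the share of such probes was the measure of signal per array, and the number of arrays limits the precision.

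The titles gave the rat and an array serial number, and the labels the diet and time. There were 89 arrays for 82 rats and times, and the 7 second arrays of a rat at a time were averaged with the first. Serial numbers fell into 3 series (A, B and C), which were taken as a possible batch. The third letter of the rat names was the letter A for all 7 wk rats of series C. It was the letter T for all 7 wk rats of series A and for all 28 wk rats. What this letter stands for is not known here. The description of 6 arrays labelled 7 wk named week 8, and of 7 arrays labelled 28 wk week 29; the labelled time was used. The names of 19 rats occurred at both later stages. For these the correlation of a rat's deviations from its group across the stages, over probes, had a median of 0.046 (from -0.43 to 0.24) against -0.0021 for different rats, and the estimated correlation within rats was 0.0098, so the pairing carried little weight. Equal names were taken as the same rat, which these correlations do not show.

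The diets were compared at each stage in a separate fit with limma (lmFit and eBayes) with terms for diet and array series and 1 value per rat, on probes above background in at least 50% of the arrays of at least 1 group and missing in under 50% of the rats. Stage effects over both diets, and differences of the diet effect between stages, came from a fit of all groups with array series as a term and the rat as a random block. All tests were two-sided, with p adjusted by the Benjamini-Hochberg method over the probes of a comparison and a threshold of 0.05. The share of probes above background was compared by exact permutation where the number of regroupings allowed, otherwise with 100000 resamples.

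The rule for naming genes was fixed before the data were examined, as were the lists, the tests of the comparisons and the other settings tried, save those named below as added. It took a single probe per gene symbol, the one with the smallest p. For a diet effect it named the 12 largest differences in each direction among the genes that passed, or, with fewer than 24 passing, all of those and the 10 genes of smallest p in each direction. For a stage effect it named the 10 largest in each direction, and for a difference of diet effects the 5 largest, or the 3 of smallest p in each direction where none passed. From each list it named at most 4 members of smallest p, and those that passed adjusted over the list alone.

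There were 20 gene lists, written from textbook knowledge: colonocyte and epithelial markers; goblet and enteroendocrine markers; small intestine, stomach and pancreas markers; squamous epithelium and hair markers; leukocyte markers; erythroid markers; stroma, muscle and endothelium markers; ribosomal proteins; oxidative phosphorylation; fatty acid oxidation and PPAR targets; sterol and fatty acid synthesis; eicosanoid synthesis and receptors; short-chain fatty acid uptake, sensing and histone deacetylases; apoptosis; DNA damage response and repair; cell cycle and proliferation; Wnt signalling, stem cell and crypt markers; inflammation and NF-kB; xenobiotic metabolism and oxidative defence; oncogenes, tumour suppressors and growth factor signalling. They were tested with camera (limma) with a preset correlation of 0.01, with a single probe per gene of highest mean signal, and for stage effects with cameraPR. Missing values, at most 3.54% of a stage, were filled with fitted values for this test, and p was adjusted over the lists and the 3 comparisons. Camera with an estimated correlation and fry were run beside it.

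Alternatives were the scanner's normalized intensity (floor 0.01), scaling to a common median, no filter and a stricter filter on dim probes, no array series term, the title prefix as a further term, each array series alone, all groups in a fit with the rat as a block, no block, the rats whose names occur at both later stages alone, array quality weights, the first array of each rat, no arrays described with another week, an intensity trend with a robust prior, no arrays of low signal, and probe means per gene. Added after seeing the data were fits without an array that resembled no other, with the share above background as a term, with series A split by its local background at 65, and of the stages within each series. The term for array series was put into the fit of the rats named at both later stages only after a first run without it.

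The steps were tested on simulated data drawn from the mean and SD of each probe, in which 200 probes were changed. Changes of 1 on the log2 scale were recovered in 85%, 66% and 54% of cases for the diet effects at 24 h, 7 wk and 28 wk, and changes of 2 in 98%, 100% and 98%, with 11 to 16 false calls. For differences of the diet effect, changes of 1 were recovered in 33% to 48% of cases. With 200 changed probes the adjusted threshold is looser than where few pass, so these shares may overstate what could be seen. In the real fit at 24 h, where 1 probe passed, Kntc1 at 1.11 and Dbi at 1.09 did not. Software was R 4.3.3 with limma 3.58.1 and version 1.17.8 of the data.table package.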

Results

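Gene expression was measured in RNA with a poly(A) tail from colon cells that Sprague Dawley rats had shed into their feces, on 89 single-colour CodeLink arrays. The rats ate 1 of 2 diets, labelled FO/P (fish oil and pectin, after the series title) and CO/C, and received 2 subcutaneous injections of azoxymethane, a carcinogen used to induce colon tumors in rodents, at 15 mg/kg. Feces were taken 24 h, 7 wk and 28 wk after the injections, the stages that the study design names as initiation, aberrant crypt foci and tumor. With repeat arrays of a rat averaged, the groups held 9 FO/P and 11 CO/C rats at 24 h, 18 and 16 at 7 wk, and 15 and 13 at 28 wk, and 19 rat names occur at both later stages. These numbers of rats limit the precision of every comparison. Signals are given on the log2 scale, and a difference of a diet is always FO/P minus CO/C.

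The share of probes above background served as a measure of the signal that each rat's RNA gave. At 24 h it was 44.3% ± 7.65 (SD, n = 9) in FO/P rats and 51.0% ± 9.46 (n = 11) in CO/C rats, a difference of -6.76 percentage points (two-sided exact permutation p = 0.101, adjusted p = 0.303). At 7 wk the shares were 33.6% ± 8.93 (n = 18) and 38.3% ± 15.9 (n = 16), a difference of -4.72 points (permutation p = 0.288, adjusted p = 0.432). At 28 wk they were 33.0% ± 14.2 (n = 15) and 35.7% ± 14.4 (n = 13), a difference of -2.69 points (permutation p = 0.62, adjusted p = 0.62). Serial numbers in the titles put the arrays into 3 series, A with 38 arrays, B with 13 and C with 38, whose median shares were 25.5%, 42.1% and 46.1%. Both diets were present in each series used at a stage. At 24 h series B held 7 FO/P and 6 CO/C rats, and series C 2 and 5. Within series the diet difference was -5.71 points in B (exact permutation p = 0.269) and -2.42 in C (exact permutation p = 0.619) at 24 h. At 7 wk it was -1.06 points in A (exact permutation p = 0.814) and -9.65 in C (exact permutation p = 0.0345), and at 28 wk -1.64 in A (exact permutation p = 0.818) and -0.73 in C (exact permutation p = 0.889). The first principal component of 1580 probes measured on all arrays held 35.9% of the variance, and array series accounted for 90.2% of that component against 0.19% for diet.

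**Figure D1:**
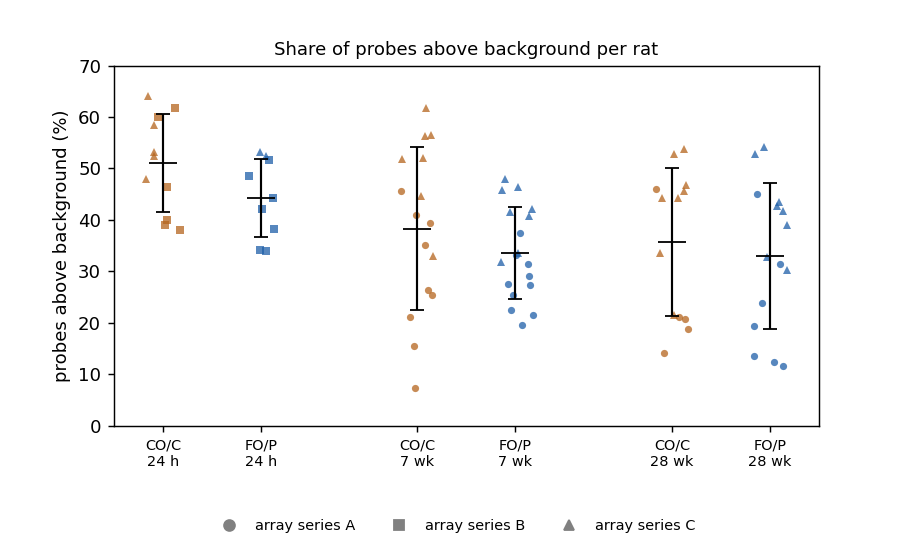
Share of probes above background in percent for each rat, by stage and diet, with the mean and SD of each group as bars and the array series as point shapes. Group means ran from 33.0% (FO/P at 28 wk) to 51.0% (CO/C at 24 h), and the median share was lowest in series A (25.5%).

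The comparison of the diets at 24 h asked how gene expression differed at initiation. Genes of protein synthesis and respiration leaned to higher signals in FO/P rats. Of 28 ribosomal protein genes measured, 27 had a difference above 0, with a median of 0.415, and Rps19 (probe GE22118) was 12.78 ± 0.324 (SD, n = 9) in FO/P rats and 12.0 ± 0.421 (n = 11) in CO/C rats. Genes of oxidative phosphorylation lay above 0 in 32 of 34 cases with a median of 0.30, and Cox8a, a subunit of cytochrome c oxidase, differed by 0.65 (standard error 0.233). Cell cycle genes lay above 0 in 24 of 27 cases with a median of 0.235, and Birc5, an inhibitor of apoptosis needed for cell division, differed by 1.40 (standard error 0.351).

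These 3 lists passed the list test, which asks whether a list's genes lie higher or lower than the other genes. The adjusted camera p was 7.53e-08 for ribosomal proteins, 0.000342 for oxidative phosphorylation and 0.00175 for the cell cycle list. For each of them it was adjusted p = 0.807 with an estimated correlation, and fry, which tests the list's genes on their own, gave adjusted p = 0.254, 0.279 and 0.254. No member of the 3 lists passed over all probes. Adjusted over the list alone, 2 ribosomal genes passed (Rps19 at 0.81 and Rps27 at 0.62), 0 of oxidative phosphorylation and 1 of the cell cycle list (Birc5, which is also the only such member of the apoptosis list). Further ribosomal members were Rpl23 at 0.61 and Rps18 at 1.64. The other leading members of oxidative phosphorylation were Cox7b at 0.64, Cox6c at 0.56 and Cox7a2 at 1.11, and those of the cell cycle list were Ccnd2 at 1.06, Mcm4 at 0.31 and Cdc20 at 0.42. The marker lists of other cell types were not called at 24 h, while the share of probes above background differed by -6.76 points. Within series B the adjusted camera p was 2.54e-06, 8.32e-05 and 0.000258 for ribosomal proteins, oxidative phosphorylation and the cell cycle list. Within series C it was 0.000758, 0.369 and 0.995, with the cell cycle list towards lower signals there. The values of series C rest on 2 FO/P rats.

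Among 18000 probes tested at 24 h, limma called 1 and no gene with a symbol. That probe, GE1287049, fell by 3.72 in FO/P rats (standard error 0.527, adjusted p = 0.021, 6.97 ± 0.655, n = 9, against 10.55 ± 1.74, n = 9); it was named after its values were seen. At an unadjusted p under 0.05 there were 1515 probes, 707 higher and 808 lower, where chance gives 900 on average. Probes move together, so chance alone can take this count far from 900. It was not compared with random splits and is no evidence of a diet effect. The genes nearest to the threshold on the higher side were Luc7l2 (GE14298), a splicing factor, at 0.88 (standard error 0.153, adjusted p = 0.101), and Fut2 (GE1138946), a fucosyltransferase that makes mucosal blood group antigens, at 0.72 (standard error 0.131, adjusted p = 0.119). Luc7l2 was 10.03 ± 0.24 (n = 9) in FO/P rats against 9.08 ± 0.419 (n = 11), and all 9 FO/P rats lay above the CO/C median. The remaining 8 genes on this side differed by 0.81 to 1.11, among them Kntc1, a kinetochore protein, at 1.11 and Dbi, the acyl-CoA-binding protein, at 1.09, with adjusted p from 0.142 to 0.155. On the lower side the 10 genes ran from -0.48 (Serpinb1a) to -1.23 (Lhfpl2), with adjusted p from 0.189 to 0.296. They included Ereg, a ligand of the epidermal growth factor receptor, at -1.18 (standard error 0.281, adjusted p = 0.246) and Mdm2, the ubiquitin ligase of p53, at -0.73 (standard error 0.18, adjusted p = 0.289). A further probe gave -0.465 for Lhfpl2 and -0.41 for Mdm2. Within series B and C the differences were 0.741 and 1.19 for Luc7l2, 0.966 and 1.37 for Dbi, and -1.43 and -0.686 for Ereg. Those of series C rest on 2 FO/P and 5 CO/C rats.

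At 7 wk, the stage of aberrant crypt foci, 4 members of the fixed list on xenobiotic metabolism rose in FO/P rats. Abcb1a (GE1151117), the P-glycoprotein efflux pump, was 2.53-fold higher (10.5 ± 0.978, SD, n = 18, against 9.19 ± 0.937, n = 15). Abcg2 (GE1274581), the efflux pump also called breast cancer resistance protein, was 2.4-fold higher (8.95 ± 0.845, n = 18, against 7.69 ± 0.979, n = 16). Ugt1a6 (GE19581), a glucuronosyltransferase, was 1.85-fold higher (8.07 ± 0.49, n = 17, against 7.19 ± 0.631, n = 15), and Aldh1a1 (GE21291), which oxidizes retinal to retinoic acid, 2.45-fold (8.05 ± 1.43, n = 17, against 6.76 ± 0.764, n = 15). Bst2 (GE1185939), an interferon-induced membrane protein that tethers virus particles, fell by 1.98 (6.36 ± 0.315, n = 18, against 8.35 ± 1.63, n = 16), and 11 CO/C rats lay above the highest FO/P rat. It was above background in 5 of 20 FO/P arrays, which limits the size of the fall that can be read.

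**Figure D2:**
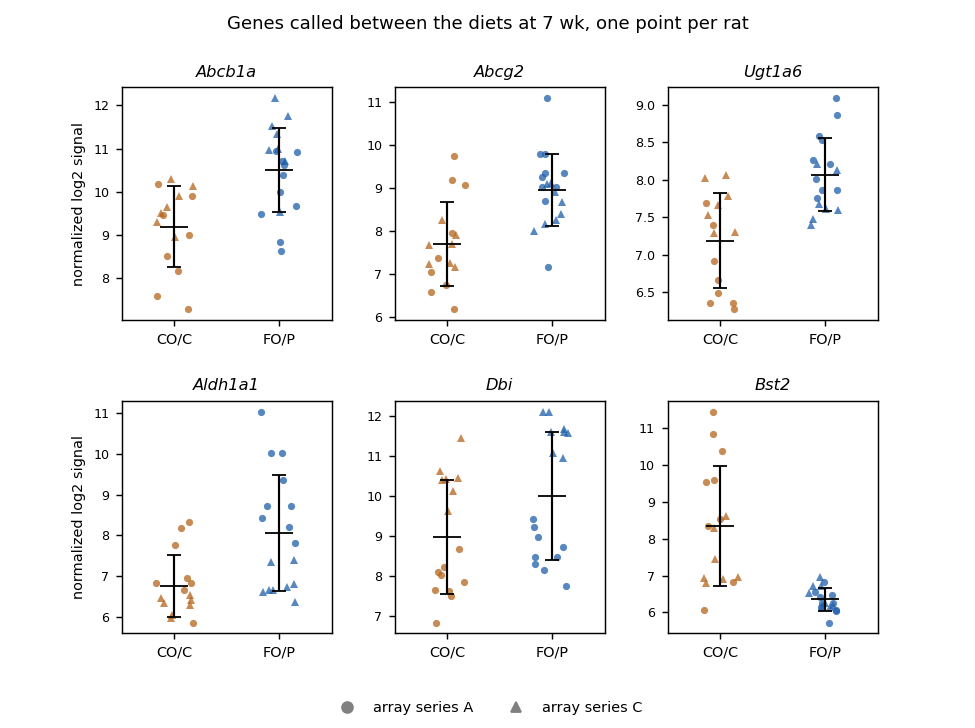
Normalized log2 signal of 6 genes called between the diets at 7 wk, each point a rat, bars the group mean and SD, point shapes the array series A or C. Abcb1a, Abcg2, Ugt1a6, Aldh1a1 and Dbi were higher and Bst2 was lower in FO/P rats, with most rats on the side of the difference.

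Of 13455 probes tested at 7 wk, 43 passed, 19 higher and 24 lower in FO/P rats. Of the higher probes 18 had a gene symbol, and of the lower ones 4, where 59.2% of all tested probes had one. The scanner's own scaling called 2 higher and 26 lower, and scaling to a common median 170 higher and 100 lower. The 21 genes among them had adjusted p from 0.012 to 0.0435. Apart from Bst2, above background in 5 of 20 FO/P arrays, they changed by 1.7-fold to 3.59-fold. Among the higher genes, Sarnp was above background in 6 of 18 CO/C arrays, Aldh1a1 in 9 and Ugt1a6 in 10. Where the signal of a diet group lay near background, the size of the difference is limited by it. The adjusted p of the 4 genes above was 0.0265 for Abcb1a, 0.0435 for Abcg2 and Ugt1a6, and 0.0286 for Aldh1a1, with standard errors of 0.276, 0.295, 0.205 and 0.277. They were above the CO/C median in 16 of 18, 17 of 18, 17 of 17 and 16 of 17 FO/P rats. For Bst2 the adjusted p was 0.012 (standard error 0.358), with 18 of 18 FO/P rats below the CO/C median.

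Of the other genes that passed at 7 wk, Dbi, the acyl-CoA-binding protein, rose by 0.95 (standard error 0.185, adjusted p = 0.0187), and Cmpk1 (GE16450), a pyrimidine nucleotide kinase, by 1.84 (standard error 0.366, adjusted p = 0.0187). Rmdn3 (GE1109586), a tether between mitochondria and the endoplasmic reticulum, rose by 1.27 (standard error 0.233, adjusted p = 0.012), and its other probe rose by 1.47. Sem1 rose by 1.60 and Psmd14 by 0.78, both parts of the proteasome, Eif4a2, a helicase of translation initiation, by 1.42, and Srp14, of the signal recognition particle, 2.01-fold. The other genes that rose were Pnrc2 (1.51), Kgd4 (1.2), Serinc3 (1.27), C2h4orf3 (1.15), Tbca (1.02) and Sarnp (0.76). Besides Bst2, the genes that fell were Trak1 (GE1182914) at -1.56, Crebbp (GE1200421), a histone acetyltransferase, at -1.17 and Bmp1 (GE16556), a procollagen protease, at -0.87. Other probes of Trak1 and Crebbp gave -0.28 for the former and 0.15 and 0.18 for the latter. Bst2 was above background in 16 of 18 CO/C arrays, and Bmp1 in 8 of 20 FO/P arrays against 17 of 18. Lower genes just short of the threshold were Vps9d1 at -1.06 (adjusted p = 0.0585), Pttg1ip at -1.03 (0.0585), Rgcc at -0.86 (0.063), Best2 at -0.78 (0.063), Epb41l1 at -1.01 (0.0655) and Ppic at -0.91 (0.0682). Other probes gave 0.215 for Pttg1ip, -0.66 and -0.03 for Epb41l1 and -0.35 for Vps9d1.

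At 7 wk 3 gene lists passed by camera with the preset correlation, all towards higher signals in FO/P rats, and each had adjusted p = 0.807 with an estimated correlation. With array quality weights the adjusted camera p was 0.756 for colonocyte markers, 0.366 for oxidative phosphorylation and 0.0497 for xenobiotic metabolism. With the first array of each rat it was 0.0535 for colonocyte markers. The xenobiotic metabolism and oxidative defence list had 24 of 33 members above 0 and 9 below, with a median of 0.34 (adjusted camera p = 0.000342). Of its members 4 passed over all probes (Abcb1a, Aldh1a1, Ugt1a6 and Abcg2), and 7 adjusted over the list alone, with Gclm, of glutathione synthesis, at 1.04, Cyp1b1 at 0.605 and the peroxidase Prdx1 at 1.02. Oxidative phosphorylation had 31 of 33 members above 0 and a median of 0.355 (adjusted camera p = 0.000342). There 0 passed over all probes and 5 adjusted over the list alone, which were Cox7a2 (1.19), Ndufa2 (0.75), Cox5a (1.11), Ndufa5 (1.00) and Ndufb8 (0.58). Colonocyte and epithelial markers had 25 of 28 members above 0 and a median of 0.43 (adjusted camera p = 0.00142). Here 0 passed over all probes and 1 adjusted over the list alone, the water channel Aqp8 at 1.74 (standard error 0.431, 9.84 ± 1.30, n = 17, against 8.10 ± 1.21, n = 13). Other leading epithelial members were the adhesion molecule Epcam at 0.91, villin (Vil1) at 0.83 and Cldn4 at 0.78. Fry gave adjusted p = 0.162, 0.254 and 0.273 in the order named. For change in either direction, fry gave adjusted p = 7.58e-05 for xenobiotic metabolism and 0.0316 for oncogenes, tumour suppressors and growth factor signalling. The leukocyte, erythroid, stroma, squamous and small intestine marker lists were not called beside these groups, and the share of probes above background differed by -4.72 points.

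Array series entered the fit as a term, and all 21 genes had the same sign within series A, as had all 20 that could be tested in series C. The genes were chosen in a fit of these same rats, so equal signs are largely given by that choice. Within A and C the differences were 1.25 and 1.45 for Abcb1a, 1.49 and 0.985 for Abcg2, 1.54 and 0.0596 for Ugt1a6, 1.97 and 0.526 for Aldh1a1, 0.783 and 1.15 for Dbi, and -2.79 and -0.952 for Bst2. The list calls were made in series A (adjusted camera p = 0.00811 for xenobiotic metabolism, 0.00619 for oxidative phosphorylation, 0.000645 for colonocyte markers) and not in series C (0.0632, 0.369 and 0.995), where limma called 0 probes (2540 at an unadjusted p under 0.05). The rats of these series also differed in the third letter of their names, so array series and set of rats cannot be told apart here. The second array of CO/C rat 13 resembled no other array (r = -0.0125 with the first array of that rat). Without it the adjusted p was 0.0782 for C2h4orf3, 0.0882 for Psmd14, 0.0634 for Sem1, 0.0562 for Tbca, Bmp1 and Crebbp, and 0.0655 for the colonocyte list. Without the arrays whose description names week 8 the 21 genes had the same sign, with folds of at least 1.56, but limma called 0 probes (2118 at an unadjusted p under 0.05, smallest adjusted p = 0.0585 among these genes). With the scanner's own scaling 21 kept their sign and 4 of the 21 passed. These were the lower genes Bst2, Bmp1, Crebbp and Trak1, and none of the higher genes passed, with adjusted p = 0.0614 for Abcb1a, 0.0743 for Aldh1a1, 0.0921 for Abcg2 and 0.173 for Ugt1a6. Their differences with this scaling were 1.72, 2.65, 1.79 and 1.33, each larger than with quantile normalization.

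**Figure D3:**
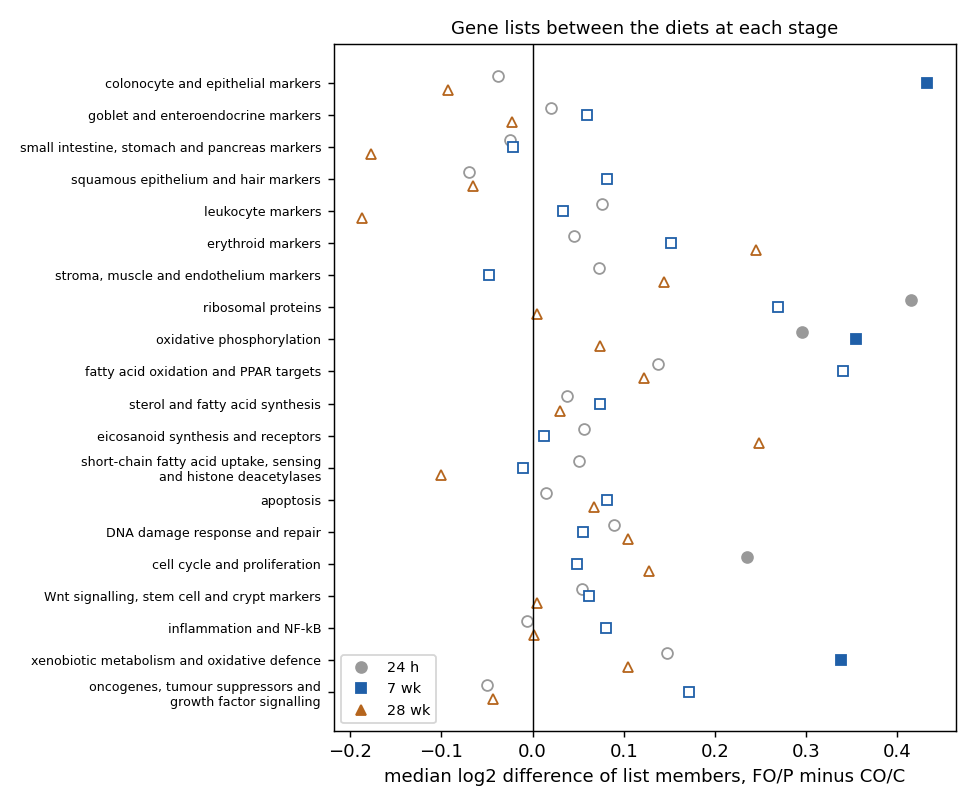
Median log2 difference between the diets (FO/P minus CO/C, horizontal axis) over the measured members of each of 20 gene lists, with circles for 24 h, squares for 7 wk and triangles for 28 wk, filled where the adjusted camera p with the preset correlation was under 0.05. The 6 filled points, 3 at 24 h and 3 at 7 wk, lie between 0.235 and 0.43, and each has adjusted p = 0.807 with an estimated correlation.

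At 28 wk, the tumor stage, the genes called between the diets were lower in FO/P rats. Ubac2 (GE1203548), a membrane protein of the endoplasmic reticulum, was lower by 2.11 in FO/P rats, a 4.3-fold difference (8.94 ± 0.671, SD, n = 15, against 11.06 ± 0.747, n = 13), and all 13 CO/C rats lay above the highest FO/P rat. Its further probe differed by only -0.11 (standard error 0.25). Nfatc2 (GE1129650), a transcription factor activated by calcineurin, fell by 1.98 (6.25 ± 0.383, n = 15, against 8.29 ± 1.16, n = 13), with signal above background in 1 of 17 FO/P arrays against 12 of 14 CO/C arrays. Cbx2 (GE1245973), a Polycomb protein that binds methylated histones, fell by 2.13 (6.74 ± 0.349, n = 15, against 8.81 ± 1.43, n = 13), above background in 8 of 17 against 13 of 14 arrays. Agtrap (GE1255024), which binds the angiotensin receptor, fell by 2.45 (6.62 ± 0.671, n = 15, against 9.08 ± 1.55, n = 12), above background in 5 of 17 against 12 of 14 arrays. Plgrkt (GE14256), a plasminogen receptor, fell by 1.60 (7.19 ± 0.519, n = 15, against 8.72 ± 1.09, n = 13), above background in 10 of 17 against 14 of 14 arrays.

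**Figure D4:**
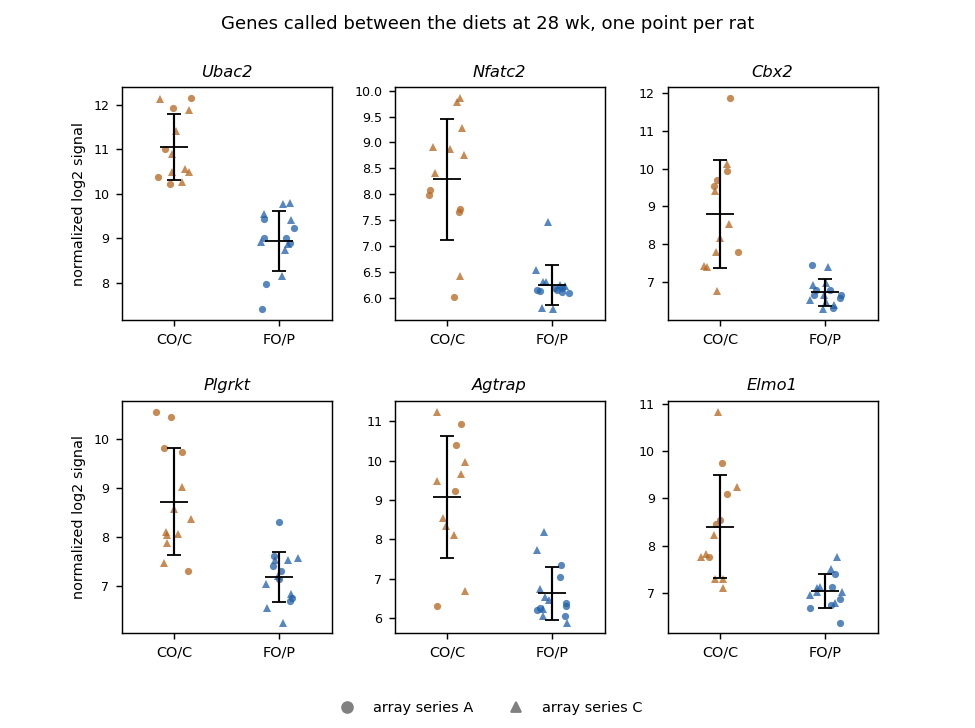
Normalized log2 signal of 6 genes called between the diets at 28 wk, each point a rat, bars the group mean and SD, point shapes the array series A or C. Ubac2, Nfatc2, Cbx2, Plgrkt, Agtrap and Elmo1 were lower in FO/P rats, and the groups did not overlap for the Ubac2 probe shown, while its further probe differed by -0.11.

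Of 13308 probes tested at 28 wk, 27 passed, 2 higher and 25 lower in FO/P rats, and 9 of the lower and 0 of the higher had a gene symbol. The adjusted p was 2.96e-05 for Ubac2 (standard error 0.266), 0.000203 for Nfatc2 (0.285), 0.00117 for Cbx2 (0.343), 0.00336 for Plgrkt (0.278) and 0.00347 for Agtrap (0.425), with every FO/P rat below the CO/C median. The other genes that fell were Kiaa0408L (2.61-fold, adjusted p = 0.00757), Atg4c (GE1184742), a protease of autophagy, by 1.36 (0.0306), Myo10 (GE1133969), a myosin of filopodia, by 1.09 (0.0422), and Elmo1 (GE1254545), which takes part in Rac activation, by 1.37 (0.0422). Ubac2 had a further probe with a difference of -0.11. Where the FO/P signal lay near background, the size of the fall is limited by it. Ubac2 was above background in all 17 FO/P and all 14 CO/C arrays. Among probes without a symbol, GE1281289 fell by 2.59 (standard error 0.245, adjusted p = 1.31e-07) and GE1297901 fell by 3.07, whereas GE1167750 rose by 1.83 and GE15731 by 1.55. These were named after their values were seen. The genes nearest to the threshold on the higher side were Fam135a at 1.15 (adjusted p = 0.0681), Sem1 at 1.25 (0.0994), the brush border protease Mep1a at 1.23 (0.113), Nr1d2 at 1.16 (0.117), Brms1 at 0.98 (0.137), Krt34 at 1.27 (0.141) and the transcription factor Fos at 1.06 (0.164). Further probes gave 0.15 for Nr1d2 and -0.42 for Fos, and on the lower side Dagla was at -0.79 (0.0681).

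No gene list passed at 28 wk. By camera the smallest unadjusted p was 0.029 for xenobiotic metabolism (23 of 36 members above 0, median 0.105, adjusted p = 0.174), and oxidative phosphorylation had 22 of 33 members above 0 and a median of 0.07 (adjusted p = 0.245). Adjusted over the list alone, 1 member of all the lists passed, the lactate carrier Slc16a3 of the short-chain fatty acid list at -0.80 (standard error 0.218). All 9 genes had the same sign within series A and within series C, where the differences were -2.43 and -1.87 for Ubac2, -1.34 and -2.45 for Nfatc2, -3.01 and -1.49 for Cbx2, -2.25 and -1.13 for Plgrkt, and -2.7 and -2.29 for Agtrap. As the 9 genes were chosen in a fit of these same rats, equal signs are no separate check. Without the arrays whose description names week 29 they had the same sign with folds of at least 1.77, and 4 passed. The scanner's own scaling called 60 probes, of which 58 were lower, and 7 of the 9 genes passed with it, without Atg4c (adjusted p = 0.0783) and Myo10 (0.177). After scaling to a common median 6 passed, without Atg4c (0.203), Myo10 (0.115) and Elmo1 (0.119).

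The marker lists of other cell types were not called between the diets at any stage. Few of their members could be tested. At 7 wk these were 9 goblet, 10 small intestine, 7 squamous, 8 leukocyte, 3 erythroid and 6 stroma members. With so few, the lack of a call does not show that the mix of cells was the same. Goblet and enteroendocrine markers had medians of 0.02, 0.06 and -0.02 at 24 h, 7 wk and 28 wk (adjusted camera p = 0.661, 0.88 and 0.437), small intestine, stomach and pancreas markers -0.025, -0.02 and -0.18 (0.437, 0.947 and 0.339), and squamous and hair markers -0.07, 0.08 and -0.06 (0.85, 0.922 and 0.922). Leukocyte markers were at 0.08, 0.03 and -0.19 (0.922, 0.947 and 0.553), erythroid markers at 0.05, 0.15 and 0.245 (0.85, 0.922 and 0.437), and stroma, muscle and endothelium markers at 0.07, -0.05 and 0.14 (0.85, 0.573 and 0.437). Colonocyte markers were at -0.04 at 24 h and -0.09 at 28 wk (0.922 and 0.506). Adjusted over the list alone, 1 gene of the other cell types passed, the lactase gene Lct at 24 h (-1.19, standard error 0.35).

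Lists for lipid metabolism and signalling were not called by camera either. Fatty acid oxidation and PPAR targets had medians of 0.14, 0.34 and 0.12 at the 3 stages (adjusted camera p = 0.146, 0.246 and 0.604), and at 7 wk 3 members passed adjusted over the list alone, the fatty acid binding protein Fabp1 at 1.10 and the thiolases Acaa1b at 1.04 and Acaa2 at 1.2. Eicosanoid genes had medians of 0.06, 0.01 and 0.25 (0.85, 0.933 and 0.437), with Cyp2j4 at 0.97 and the phospholipase Pla2g2a at -0.84 passing over the list alone at 7 wk. Sterol and fatty acid synthesis gave 0.04, 0.07 and 0.03 (0.661, 0.966 and 0.834), and short-chain fatty acid uptake and histone deacetylases 0.05, -0.01 and -0.10 (0.992, 0.85 and 0.437). Ribosomal proteins gave 0.27 at 7 wk and 0.0048 at 28 wk (0.146 and 0.724), and xenobiotic metabolism 0.15 at 24 h (0.246). DNA damage and repair genes gave 0.09, 0.06 and 0.105 (0.339, 0.663 and 0.506), with Gadd45a at 1.11 and Ddb1 at 0.55 over the list alone at 7 wk. The oncogene, tumour suppressor and growth factor list gave -0.05, 0.17 and -0.04 (0.0984, 0.621 and 0.741), with Jun at 0.89 and Tgfbr1 at 1.18 over the list alone at 7 wk. Apoptosis genes gave 0.015, 0.08 and 0.07 (0.922, 0.661 and 0.31), the cell cycle list 0.05 at 7 wk and 0.13 at 28 wk (0.922 and 0.661), Wnt and stem cell markers 0.05, 0.06 and 0.0046 (0.604, 0.922 and 0.922), and inflammation genes -0.0061, 0.08 and 0.0013 (0.575, 0.888 and 0.79). Median, mean and test differed in sign for the colonocyte, stroma and apoptosis lists at 24 h, for the goblet, small intestine, erythroid, short-chain fatty acid and cell cycle lists at 7 wk, and for the squamous, Wnt and inflammation lists at 28 wk, none of them called.

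The stages were compared over both diets. Every rat had received azoxymethane, so a change between stages cannot be told apart from one of age or time on the diet. From 24 h to 7 wk, Lef1 (GE1287569), a transcription factor of Wnt signalling, fell by 0.92 (standard error 0.164, adjusted p = 0.000745), Hr (GE21015), a nuclear corepressor, by 1.04 (0.173, adjusted p = 0.000621) and Dhx16 (GE1290616), a splicing helicase, by 1.25 (0.196, adjusted p = 0.000188). The other genes that fell were Yif1a by 1.70, Tbc1d5 by 1.38, Rbm26 by 1.27, Stra6l by 1.13, Kntc1 by 1.02, Adpgk by 0.77 and Slc43a2 by 0.65 (above background in 0 of 20 FO/P arrays at 7 wk), and Plppr5 (GE1103238) rose by 0.74 (standard error 0.152, adjusted p = 0.0124). Mean Lef1 signals lay near the lower end of the scale, at 6.74 ± 0.695 (n = 9) in FO/P and 6.47 ± 0.47 (n = 11) in CO/C rats at 24 h, and 6.35 ± 0.374 (n = 18) and 6.26 ± 0.235 (n = 15) at 7 wk. These means, over all series, differ by less than the fall of 0.92, which was adjusted for array series. That fall rested largely on series C, which held 2 FO/P and 5 CO/C rats at 24 h. Squamous and hair markers lay above 0 in 7 of 7 cases with a median of 0.26 (adjusted camera p = 0.0472), among them Sprr1a at 0.76, Krt15 at 0.70, Krt14 at 0.58 and Krt4 at 0.26. Cell cycle genes lay below 0 in 17 of 28 cases with a median of -0.19 (adjusted camera p = 0.0379), among them Birc5 at -0.93, Cdk1 at -0.64 and Aurkb at -0.52, with Foxm1 at 0.43. Both had adjusted p = 0.386 with an estimated correlation. No member of either passed over all probes or adjusted over the list alone; in other lists Tff1 (0.55), Cd5 (-0.52), Ccl20 (1.79) and Lef1 did over the list alone.

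Limma called 27 of 18434 probes from 24 h to 7 wk, 5 higher and 22 lower, and 11 had a symbol. The scanner's own scaling called 13 higher and 11 lower, and scaling to a common median 69 higher and 114 lower. The other probes of Yif1a and Dhx16 gave -0.03 and -0.56. Of the array series, C alone held rats of both stages, with 2 FO/P and 5 CO/C rats at 24 h. With array series as a term, the comparison rested largely on the rats of C. Within C, 7 of the 11 genes could be tested and all 7 had the same sign, with -1.02 for Lef1 and -1.24 for Tbc1d5. As these are largely the same data, equal signs are no separate check. Hr, Dhx16, Plppr5 and Yif1a were not tested there. With the share of probes above background as a term 6 of the 11 passed and all 11 kept their sign. Those that did not pass were Plppr5 at 0.52 (adjusted p = 0.414), Yif1a at -1.12 (0.636), Tbc1d5 at -1.35 (0.0714), Kntc1 at -0.997 (0.0677) and Slc43a2 at -0.61 (0.0917). The squamous list had adjusted camera p = 0.00395 within series C, 0.0219 with the scanner's own scaling and 0.0825 after scaling to a common median, and the cell cycle list 0.381, 0.102 and 0.379. With the share of probes above background as a term these lists had adjusted camera p = 0.207 and 0.0212, and with the stricter filter on dim probes 0.0784 each.

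From 7 wk to 28 wk, Hk1 (GE1320312), the hexokinase of glycolysis, fell by 1.08 (standard error 0.211, adjusted p = 0.0112), and its 8 probes were between -0.56 and -1.16. Ncor1 (GE1126437), a corepressor of nuclear receptors, fell by 1.30 (standard error 0.244, adjusted p = 0.0112), with its other probes at -1.27, -0.29 and 0.09. Uqcrc1 (GE1263905), of respiratory complex III, fell by 1.13 (standard error 0.242, adjusted p = 0.0194), from 11.3 ± 1.08 (n = 18) and 11.16 ± 1.60 (n = 16) in FO/P and CO/C rats to 10.46 ± 1.97 (n = 15) and 10.47 ± 2.38 (n = 13). Rpl4, a ribosomal protein, rose by 0.98 (standard error 0.26, adjusted p = 0.0433) and the small GTPase Rap1a (GE1160033) by 0.89 (standard error 0.194, adjusted p = 0.0194). The remaining genes named among the lowest fell by 1.10 (Trrap) to 1.28 (Rcor1), with Srrm2, Pdpk1, Lzts2, Slc5a3 and Tsc22d4 between them. Those among the highest rose by 0.70 (Naa20, Asap1) to 1.07 (Gabrq), with Chmp2b, the kinase Rock2, Aqp6, Vasn and Mri1 between them; other probes of Rock2 gave 0.25, 0.13 and -0.62. A further probe gave 0.15 for Rap1a, 0.08 for Chmp2b, -0.08 for Rcor1 and -0.745 for Trrap, and 2 of Srrm2 gave -0.455 and 0.06.

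Of 18434 probes, 151 passed from 7 wk to 28 wk, 56 higher and 95 lower, with 27 and 60 gene symbols, and camera called no list (smallest adjusted p = 0.0686, short-chain fatty acid genes, median -0.215, with Hdac4 at -0.89 over the list alone). List members that passed over all probes, with the same members adjusted over the list alone, were Rpl4 and Rpl11 (0.60) of the ribosomal list, Uqcrc1, Hadha of fatty acid oxidation (-0.68, adjusted p = 0.0195) and Cyp3a18 (0.55, adjusted p = 0.0203). Adjusted over the list alone there were in addition the epithelial transcription factors Klf4 (-0.70) and Klf5 (-0.74), Sprr1a (-0.60), Krt10 (0.36), Cd163 (0.26), Cd36 (0.44) and Dhcr7 (0.66). All 20 named genes had the same sign within series A and within series C, with -1.64 and -0.508 for Hk1, -1.88 and -0.475 for Uqcrc1, and 0.675 and 1.3 for Rpl4. They were chosen in a fit of these same rats, so equal signs in any part of the rats are no separate check. The scanner's own scaling called 0 probes (2426 at an unadjusted p under 0.05), with 20 of 20 signs kept, and scaling to a common median called 9 higher and 26 lower. Limma called 0 probes in series A alone (1104 at an unadjusted p under 0.05) and 105 in series C. In series C the 7 wk rats all had the letter A in their names and the 28 wk rats the letter T. Stage and set of rats thus cannot be told apart within series C, whose rats are also in the fit over both series. In the 19 rats named at both stages the 20 genes had the same sign, but limma called 0 probes (1474 at an unadjusted p under 0.05), with adjusted p = 0.247 for Hk1, 0.199 for Ncor1 and 0.261 for Uqcrc1, and Rpl4 at 0.32 (0.844). With the share of probes above background as a term limma called 30 probes, and 8 of the 20 genes passed, among them Hk1, Ncor1, Uqcrc1, Rpl4 and Rap1a.

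From 24 h to 28 wk, Guca2b (GE1153287), which encodes uroguanylin, an epithelial peptide of salt and water secretion, rose by 1.31 (standard error 0.317, adjusted p = 0.0264), and Ocm (GE1162560), a calcium-binding protein, by 1.40 (standard error 0.234, adjusted p = 0.000191). Trpv6 (GE13408), the calcium channel of absorbing epithelium, fell by 1.68 (standard error 0.407, adjusted p = 0.0264), and Satb1 (GE1131461), an organizer of chromatin, by 1.55 (standard error 0.331, adjusted p = 0.0071). Trpv6 was 10.3 ± 0.77 (n = 9) and 10.62 ± 0.634 (n = 11) at 24 h and 8.36 ± 1.31 (n = 15) and 9.48 ± 0.95 (n = 13) at 28 wk in FO/P and CO/C rats. Ubac2, lower in FO/P rats at 28 wk, rose by 2.09 over both diets (standard error 0.522, adjusted p = 0.0312), from 7.64 ± 0.602 (n = 9) and 8.22 ± 0.749 (n = 10), and its further probe gave -0.16. Small intestine, stomach and pancreas markers lay above 0 in 12 of 12 cases with a median of 0.43 (adjusted camera p = 0.0181, and adjusted p = 0.283 with an estimated correlation). Fabp2 was at 0.88, Gkn1 at 0.58, Tff1 at 0.56 and Si at 0.22. Of the members 0 passed over all probes and 1, Tff1, adjusted over the list alone. Other marker lists, not called, also had medians above 0. These were stroma, muscle and endothelium at 0.499 (adjusted camera p = 0.0629), erythroid at 0.44 (0.424), squamous at 0.33 (0.163) and leukocyte at 0.17 (0.51). Goblet and colonocyte markers had medians of -0.09 and -0.14 (0.984 and 0.863).

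Of 18434 probes, 178 passed from 24 h to 28 wk, 26 higher and 152 lower, with 11 and 26 gene symbols. The other genes that rose were S100a7l2 (1.62), Drc3 (1.12), Opn4 (0.89), Plppr5 (0.81), Crybb3 (0.79), P2rx7 (0.76) and Fzd10 (0.71). Those that fell most were Yif1a (-2.43), Tbc1d5 (-1.91), Rbm5 (-1.82), Emid1 (-1.63), Idua (-1.56), Rhbdl2 (-1.40), Rbm26 (-1.17) and Arhgap9 (-1.16), where another probe gave 0.12 for Yif1a and -0.50 for Rbm5. Over the list alone Cd5 (-0.54), Foxm1 (0.57), Guca2b and Lef1 (-0.90) also passed. The small intestine, stomach and pancreas list had adjusted camera p = 0.0187 within series C, 0.168 with the share of probes above background as a term and 0.0784 with the stricter filter on dim probes. With that term limma called 48 probes, and 7 of the 20 genes passed, among them Ocm and Satb1. Others did not, with Guca2b at 1.06 (adjusted p = 0.155), Trpv6 at -1.57 (0.0917), Ubac2 at 1.57 (0.208), Yif1a at -1.64 (0.234), Opn4 at 0.39 (0.828), Plppr5 at 0.52 (0.41) and Crybb3 at 0.08 (0.994), and Crybb3 was at 0.12 with the scanner's own scaling and 0.36 after scaling to a common median. The share was 44.3% and 51.0% in FO/P and CO/C rats at 24 h and 33.0% and 35.7% at 28 wk. Within series C 16 of the 20 genes could be tested and all 16 had the same sign, with 1.4 for Guca2b, -1.76 for Trpv6, -1.7 for Satb1 and 2.09 for Ubac2. Series C alone held rats of 24 h and 28 wk, so these are largely the same data and no separate check. Yif1a, Opn4, Plppr5 and Crybb3 were not tested there. Under the scanner's own scaling the median of all probes was -0.37 against -0.014, 20 of 20 signs were kept with 7 passing, and 26 probes were higher and 80 lower. Scaling to a common median called 1692 higher and 796 lower. Among lists that were not called, median, mean and test differed in sign for goblet, ribosomal and short-chain fatty acid genes from 24 h to 7 wk. They did so for colonocyte, oxidative phosphorylation, apoptosis, cell cycle, inflammation and oncogene lists from 7 wk to 28 wk, and for goblet and fatty acid oxidation genes from 24 h to 28 wk.

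Whether the diet effect changed between stages was tested as a difference of differences. From 24 h to 7 wk limma called 1 of 18434 probes, GE1286780, which has no symbol and was named after its values were seen. Its diet effect differed by -1.19 (standard error 0.228, adjusted p = 0.0255), with means of 7.19 ± 0.677 (n = 9) in FO/P and 6.2 ± 0.285 (n = 10) in CO/C rats at 24 h against 6.27 ± 0.228 (n = 18) and 6.41 ± 0.466 (n = 16) at 7 wk. At an unadjusted p under 0.05 there were 675 probes, where chance gives 922 on average. The gene nearest to the threshold was Kntc1, whose diet effect was lower at 7 wk by a value of -1.47 (standard error 0.307, adjusted p = 0.0736), followed by Mecr at -1.13 (0.251) and Bmp1 at -1.10 (0.73), with Rmdn3 at 1.38, Lct at 1.31 and Stac3 at 1.2 on the other side. Between 7 wk and 28 wk limma called 0 probes (1352 at an unadjusted p under 0.05, smallest adjusted p = 0.085). Stam2 was at 0.88 (adjusted p = 0.335) and Bmp1 at 0.97, Prickle3 at 1.075, Arl1 at -1.605, Rbm34 at -1.30 and Gpa33 at -1.30 (adjusted p = 0.443 each). Between 24 h and 28 wk limma also called 0 probes (854 at an unadjusted p under 0.05, smallest adjusted p = 0.19). Plgrkt was at -1.88 (standard error 0.443, adjusted p = 0.373), Nipsnap1 at -1.06 (0.43), RatNP-3b at -1.115 (0.549), Dtwd1 at 0.84 (0.626), Nsrp1 at 1.30 and Rttn at 0.72. Other probes gave 1.66 for Rmdn3, -1.05 for Arl1, -0.55 for Rbm34 and -0.41 for Nipsnap1. Adjusted over the list alone, Lct and Birc5 (-1.75) passed from 24 h to 7 wk, Vil1 (-1.30), Ahsp (1.02) and Slc16a1 (-1.45) from 7 wk to 28 wk, and Ascl2 (-1.08) from 24 h to 28 wk.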

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

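None of the tests in this part was chosen only after the result was seen. The FO/P rats at 24 h (n = 9) were searched for a rat far from the others in 25 measures. These were named genes and probes and the share of probes above background. Of the 25, 2 had such a rat. Chance gives such a rat in about 1 in 20 groups, so 2 of 25 is near what chance gives. For Serpinb1a the lowest was FO/P 24 h replicate 4, at 12.41 where the mean was 13.09 ± 0.307 (SD), and its gap to the nearest rat was 0.506 of the range of the group. For probe GE1287049, lower in FO/P rats at 24 h, the highest was FO/P 24 h replicate 7, at 8.62 where the mean was 6.97 ± 0.655, with a gap of 0.697 of the range. This rat lay towards the CO/C rats, whose mean was 10.55 ± 1.74.

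The diet effect on probe GE1286780, which has no gene symbol, differed between 24 h and 7 wk by -1.19 (standard error 0.228, adjusted p = 0.0255). Its FO/P mean was 7.19 ± 0.677 (n = 9) at 24 h against 6.2 ± 0.285 (n = 10) in CO/C rats, and at 7 wk the means were 6.27 ± 0.228 (n = 18) and 6.41 ± 0.466 (n = 16). FO/P rats at 24 h ran from 6.43 to 8.54, and CO/C rats from 5.92 to 6.80. Random splits of the rats gave at least 1 such probe in 5 of 100 cases for this difference (highest other 1), so chance cannot be excluded. For the 1 probe called at 24 h, GE1287049, they did so in 4 of 100 (highest other 2), just under the 0.05 at which chance counts as excluded. No other explanation, technical or biological, was weighed for these 3 results.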

How the results depend on the processing

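The tests with the share of probes above background as a term, with series A split by local background, without 1 array unlike the others and of the stages within an array series were chosen only after the result was seen. The counts of probes past the threshold stayed within a factor of 1.5, for the diet and stage effects and their differences, under 4 alternatives: the title prefix as a term, the first array of each rat, an intensity trend with a robust prior, and no unlike array. They ran from 31 to 48 at 7 wk, 27 to 30 at 28 wk, 21 to 31 from 24 h to 7 wk, 128 to 174 from 7 wk to 28 wk and 151 to 187 from 24 h to 28 wk. Of 3009 values over 204 results for named genes, 2469 kept their direction and side of the threshold, 413 kept their direction and fell short, 125 kept it and newly passed, and 2 turned. Those were Cdc20 at 24 h within series C (-0.23) and the difference for Bmp1 from 24 h to 7 wk within series C (0.068), both in fewer rats. Results that had not passed keep their side by failing again, and the genes were chosen in these same rats. The counts are thus no measure of robustness. With the scanner's own scaling 4 of 21 genes passed again at 7 wk and 7 of 9 at 28 wk. For the stage effects 5 of 11, 0 of 20 and 7 of 20 did, in the order above.

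With the scanner's own scaling limma called 28 probes at 7 wk, 60 at 28 wk, 0 from 7 wk to 28 wk (2426 at an unadjusted p under 0.05) and 106 from 24 h to 28 wk, and 3 for the difference between 7 wk and 28 wk; 5 stage lists passed. Scaling to a common median gave 270 at 7 wk, 183, 35 and 2488 for the stage effects from 24 h to 7 wk, 7 wk to 28 wk and 24 h to 28 wk, and 4, 2 and 1 for the differences in that order. The cause was not tested. All probes called at first had the same sign under both scalings. After scaling to a common median, the median of all probes was 0.13 (0.015 in the report) for the difference between 24 h and 7 wk and -0.15 (-0.0099) for that between 7 wk and 28 wk. With the scanner's own scaling it was -0.17 (0.0088), -0.13 (0.00092) and -0.37 (-0.014) for the stage effects.

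With no filter on dim probes, which tests more probes, limma called 0 at 24 h (2215 at an unadjusted p under 0.05), 7 at 7 wk, 64 from 7 wk to 28 wk and 91 from 24 h to 28 wk. The stricter filter gave 6 from 24 h to 7 wk, 72 from 24 h to 28 wk, 0 for the difference between 24 h and 7 wk (380 at an unadjusted p under 0.05; GE1286780 was not tested) and 1 stage list, which is none of the 3 in the report (adjusted camera p = 0.0784 each). Without a term for array series there were 2 probes at 24 h, 3 at 7 wk, 17 at 28 wk, 5482 from 24 h to 7 wk, 13 from 7 wk to 28 wk, 5982 from 24 h to 28 wk, 0 for the difference between 24 h and 7 wk (465 at an unadjusted p under 0.05) and 6 stage lists, without the cell cycle list (0.198). Series B held 24 h rats alone and series A none, so without that term stage and series are mixed. Array quality weights gave 0 at 24 h (1664 at an unadjusted p under 0.05), 1600 at 7 wk, 180 at 28 wk, 445, 702 and 2213 for the stage effects, and 28, 89 and 23 for the differences; the cause was not tested. With these weights colonocyte markers (0.756) and oxidative phosphorylation (0.366) were not called at 7 wk, and with the first array of each rat colonocyte markers were not (0.0535).

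With all groups in a fit that takes the rat as a block, limma called 3 probes at 24 h, 125 at 7 wk and 74 at 28 wk; the cause was not tested. Without the block the stage effects gave 27, 145 and 179. In the 19 rats named at both later stages, with each rat as a fixed block and thus fewer rats, limma called 0 from 7 wk to 28 wk (1474 at an unadjusted p under 0.05), and 148 of 149 probes called at first had the same sign. These rats were also in the fit that called the probes. Without the arrays described as week 8 or 29 (13 in all) there were 0 at 7 wk (2118 at an unadjusted p under 0.05) and 13 at 28 wk, from fewer rats.

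Within series A, with fewer rats, limma called 10 probes at 7 wk, 6 at 28 wk and 0 from 7 wk to 28 wk (1104 at an unadjusted p under 0.05). Within series C it called 0 at 24 h (1017), 0 at 7 wk (2540), 10 at 28 wk, 13 from 24 h to 7 wk and 384 from 24 h to 28 wk, and 0 (489) and 3 for the differences between 24 h and 7 wk and between 7 wk and 28 wk, with the count at an unadjusted p under 0.05 in parentheses. There 1 diet list passed, and the share of probes above background at 7 wk differed by -9.65 points; the cause was not tested. With the share of probes above background as a term there were 3 at 24 h, 632 at 7 wk, 92 at 28 wk, 30 from 7 wk to 28 wk, 48 from 24 h to 28 wk, 1 for the difference between 24 h and 28 wk and 5 stage lists, without the squamous (0.207) and small intestine (0.168) lists. With series A split there were 74 from 7 wk to 28 wk and 1 stage list, as the squamous and cell cycle lists were at 0.0502; the cause was not tested. With an estimated correlation, and with fry for change in the list's direction, no diet list passed (0 of 6; for change in either direction fry gave adjusted p = 7.58e-05 for xenobiotic metabolism at 7 wk), and with an estimated correlation 0 of the 3 stage lists did. The fit without arrays of low signal was not run, as 0 arrays met its rule, and series A held no 24 h rats. The diet lists were not counted with the intensity trend, with the rat as a block, without the arrays of weeks 8 and 29, with series A split, or within series A or B.

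Signal over background limits what could be seen. The share of probes above background had a median of 25.5% in series A against 46.1% in series C. On simulated data a change of 1 on the log2 scale was recovered in 54% of cases at 28 wk and in 33% for the difference between 24 h and 7 wk, so smaller changes were often missed.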

Other observations

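In this part the tests without 1 array and with the share of probes above background as a term were chosen only after the result was seen. For the 43 probes called between the diets at 7 wk, against the second array of CO/C 7 wk replicate 13 as the whole cause, 34 passed again without it, and against a difference in signal, all 43 passed again with the share of probes above background as a term. Against a difference between array series, probes called in series A alone differed in series C by a mean of 0.516 in the direction seen in A (9 of 9, exact permutation p = 0.036). In the other rats measured at 24 h the called probes differed by a mean of 0.476 in their direction at 7 wk (37 of 42, exact permutation p = 0.018, adjusted p = 0.028), so a diet effect that is present from early on may be part of the pattern. A change in the share of epithelial cells in the feces stays open, as colonocyte markers had a median of 0.43 (adjusted camera p = 0.00142), though adjusted p = 0.807 with an estimated correlation, 0.756 with array quality weights and 0.995 within series C. The RNA that the lower probes bind stays open here too: over 7 genes lower at an unadjusted p under 0.001, 2 of them called, further probes had a median of -0.0386 against -1.03.

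The 27 probes called at 28 wk were weighed next, and with the share of probes above background as a term all 27 passed again. Against a difference between array series, probes called in series A alone differed in C by 1.72 in the same direction (6 of 6, exact permutation p = 0.00031), and those called in C alone differed in A by 1.98 (7 of 7, exact permutation p = 0.0013). At 7 wk the called probes differed by a mean of 0.6 in their direction at 28 wk (25 of 25, permutation p = 0.021, adjusted p = 0.028), which may reflect a lasting diet effect, although 19 rat names occur at both stages and the tests are not independent. What stays open is the RNA that the lower probes bind, since 9 of the 25 had a gene symbol and of these Ubac2 alone had a further probe (-0.11 against -2.11). Over 6 genes lower at an unadjusted p under 0.001, 5 of them not called, further probes had a median of -0.103 against -1.29, with 4 of 6 of the same sign, too few called genes to tell whether the probes bind RNA other than the named transcript.

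The diet effect called at a stage was also looked up at the others. Probes called at 7 wk differed at 28 wk by a mean of 0.483 in the same direction (30 of 38, permutation p = 0.0041, adjusted p = 0.016), and those called at 28 wk differed at 24 h by 0.295 (23 of 25, exact permutation p = 0.051). At 24 h, 7 wk and 28 wk the difference was 1.14, 1.60 and 1.25 for Sem1, 1.09, 0.95 and 0.24 for Dbi, and -0.47, -1.98 and -1.55 for Bst2. At 24 h and 7 wk it was -0.55 and -0.75 for Ubac2, -0.52 and -1.08 for Nfatc2, and 0.30 and -0.39 for Plgrkt.

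Rats were also split at random within array series into groups of the same sizes, 100 splits with the real one included. Chance can be excluded for the diet effect at 7 wk (43 probes, 0 in the highest other split, 1 of 100 splits as large) and at 28 wk (27, highest other 1, 1 of 100). It can also be excluded for the stage effects from 24 h to 7 wk (27, highest other 16, 1 of 100), from 7 wk to 28 wk (151, highest other 49, 1 of 100) and from 24 h to 28 wk (178, highest other 12, 1 of 100). The splits of the stages did not keep to the pairing of rats named at both later stages. In those 19 rats alone limma called 0 probes from 7 wk to 28 wk. At 24 h 4 of 100 splits gave at least the 1 probe of the real one, a share just under the 0.05 at which chance counts as excluded. This is weak, as the highest other split gave 2, and limma called 0 with no filter on dim probes (2215 at an unadjusted p under 0.05) and with array quality weights (1664). Chance cannot be excluded for the 6 diet lists (9 of 100 splits, highest other 11), for the 3 stage lists (58 of 100, highest other 11) or for the 1 probe whose diet effect differed between 24 h and 7 wk (5 of 100, highest other 1). For the other differences, where limma called 0 probes (1352 and 854 at an unadjusted p under 0.05), the splits cannot decide. All 100 splits reach a count of 0 by definition, with 4 and 9 in the highest other. Splits that call several times the real count, as for the stage lists, point to a structure of the samples or to list members that move together. For the 3 stage lists the estimated correlation was 0.17 (squamous), 0.056 (cell cycle) and 0.076 (small intestine) where the preset was 0.01, and 0 of the 3 passed with it; these explanations were not told apart.

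Arrays of the same series resembled each other with a median correlation of 0.572 in A, 0.841 in B and 0.8555 in C. The 7 pairs of repeat arrays of a rat had correlations of 0.649 (FO/P 7 wk replicate 8), 0.785 (FO/P 7 wk replicate 15), 0.702 (CO/C 7 wk replicate 7), -0.0125 (CO/C 7 wk replicate 13), 0.5 (FO/P 28 wk replicate 5), 0.861 (FO/P 28 wk replicate 13) and 0.593 (CO/C 28 wk replicate 3).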
